A study of Homo sapiens with 10 samples.

How the data were processed

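RNA was measured in tumour biopsies of 5 patients with hormone receptor-positive, HER2-negative metastatic breast cancer. Each patient gave 1 biopsy before treatment (baseline) and 1 at disease progression, so 10 libraries form 5 pairs. First-line treatment was the aromatase inhibitor letrozole at 2.5 mg per day with the CDK4/6 inhibitor palbociclib at 125 mg on 21 days of each 28-day cycle, per the labels' protocols. RNA came from frozen biopsies and was made into libraries with a TruSeq RNA kit, followed by exome capture, per the labels' protocols. In exome capture, probes against exons pull down cDNA, so the level of an RNA also depends on whether the probe set covers it. The genome build was GRCh38 (hg38), per the submitters' processing notes. The aligner, the counting tool and the annotation release are not given in the sources used here.

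The deposited counts were whole reads per gene for 35245 genes, not normalised. The deposited FPKM values (fragments per kilobase and library size) equalled the counts divided by gene length plus 1 base and by the library total, within a relative tolerance of 1e-06 for 100% of 250467 nonzero values. They therefore hold no information beyond the counts. Rows of the Y chromosome and of 1 X-linked locus, 96 in all, were left out of every test and table. They held at most 0.41% of a library's counts. Of the 35149 remaining identifiers, 34165 were found in GENCODE release 29. Whether counting used strand is not given in the sources used here, so antisense and overlapping genes are uncertain. Reads of near-identical copies, such as HBA1 and HBA2, HSPA1A and HSPA1B, and HLA genes, may be split between them.

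Library totals ranged from 22153980 to 74603696 counts. No 2 libraries were duplicates: the smallest chi-square per degree of freedom over the 45 pairs of libraries was 113. The labels tie both libraries of a pair to 1 patient, which is where the pairing comes from. As a check, deviations from the group means correlated within patients 1 to 5 at r = 0.27, 0.52, 0.65, -0.06 and 0.19 across genes, which are not independent replicates.

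Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10), libraries were scaled by TMM, and a quasi-likelihood model with patient as a block was fitted (glmQLFit, robust; glmQLFTest, two-sided), which left 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called. Fold changes are progression over baseline. Intervals are 95% intervals from the same model. Levels are CPM (counts scaled to library size), and log2 CPM used a prior count of 2. Gene lists were tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, for lists with at least 5 members tested. Of the 42 lists, 39 could be tested; the epidermis, mesothelium and brain lists had too few members. A list score is the mean log2 CPM of its members, and its 5 within-patient differences were tested by an exact two-sided sign-flip test, which cannot go below 0.0625 with 32 sign patterns. Whether the libraries of a patient were more alike than others was tested over all 120 matchings (exact, one-sided).

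The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named up to 10 genes per direction that passed the test and moved the same way in all pairs, leaving out immunoglobulin and T cell receptor segments and symbols that are clone or locus identifiers. Where too few passed, each direction was filled to 5 by the smallest unadjusted p. It also named 31 panel genes of the CDK4/6 and RB pathway, proliferation and receptors, the 3 members with the smallest p in each list that passed (some of which are not described here), and the first such member of other lists described. Alternatives fixed in advance were a fit without the block, RLE and upper-quartile scaling, other count filters, limma on log2(FPKM + 1) or with a pseudocount of 0.1, DESeq2 1.42.0, limma-voom with sample weights, an epithelial score as covariate, an estimated inter-gene correlation, fry, an adjusted p under 0.1, median and FPKM list scores, Spearman, FPKM and 1000 variable genes for the likeness of libraries, and leaving out each pair. Alternatives chosen after seeing the data were hepatocyte and marrow scores as covariates, leaving out patients 1 and 4, a term for 4 libraries rich in the non-coding RNA MALAT1, and a correction for transcript GC content, which was known for 98.4% of tested genes. The term for the 4 libraries, also called the MALAT1 or library-type term, leaves the comparison to patient 2. Its results rest on 1 pair.

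The procedure was tested on simulated counts with the real patient means, library sizes and dispersions for 18543 genes. For this comparison edgeR called 0% of 67 genes changed 2-fold, 0% of 67 changed 4-fold and 39.4% of 66 changed 8-fold, with 1 false call. On the same counts DESeq2 called 7.46%, 62.7% and 93.9%, with 129 false calls among 240. A planted list of 30 genes raised 2-fold was called and 0 of 50 random lists were. Genes were simulated independently, whereas the median estimated correlation within the real lists was 0.413. The simulation therefore cannot show how often lists of correlated genes are called without a change. Figures were drawn with matplotlib 3.10.9.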

Results

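Exome-capture RNA-seq was compared between baseline and progression biopsies of 5 patients treated with letrozole and palbociclib. The comparison asks which genes and gene groups differed once tumours had progressed on oestrogen deprivation and CDK4/6 inhibition. Total counts at baseline were 22356164, 68187167, 73698835, 31858356 and 36505589 in patients 1 to 5, and at progression 22153980, 66190299, 35529532, 74603696 and 33450729. The biopsy sites are not given in the sources used here.

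No single gene passed the edgeR test with Benjamini-Hochberg adjustment among 18543 tested, and the smallest adjusted p was 0.263. At an unadjusted p under 0.05 there were 2721 genes, 1166 higher and 1555 lower at progression, where 927 are expected by chance if genes were independent. In all, 3016 genes (16.3%) moved the same way in 5 of 5 pairs, where 6.25% is expected by chance. Of 100 splits of the 10 libraries, 4 gave as many, the real one included, and the highest other gave 3262. Some splits repeat the same fit, since the side that a pair kept together is put on does not change a fit blocked on patient. The fit with 3262 is among those repeated. DESeq2 called 1893 genes, 1016 higher and 877 lower, and limma-voom called 0. The spread between patients was wide: the biological coefficient of variation was 0.626 and the median half-width of a 95% interval was 1.04 on the log2 scale. With the pair of patient 2 left out, edgeR called 40 genes, 17 higher and 23 lower. Without any other pair it called 0. The 4 progression libraries left without patient 2 are all rich in the non-coding RNA MALAT1, and no baseline library is. Progression cannot be told apart there from that split of the libraries, described below. MEG3, TERC, RMRP and MRC1, which separate these libraries, were among the 40 genes. So was the MALAT1 entry annotated as misc_RNA (8.86), but not the MALAT1 entry annotated as lincRNA. Some of the 40 carry equal values under different names, such as RMRP and RNase_MRP (5.68 each), so they are not all separate genes.

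The genes with the smallest p that were higher in 5 of 5 pairs, none of which passed by edgeR, were led by GABARAPL1, an autophagy-related gene (ENSG00000139112, chromosome 12, 10212458 to 10223130). Its level was 6.88 ± 2.17 CPM at baseline and 35.4 ± 12.8 CPM at progression (SD, n = 5), a log2 fold change of 2.30. PFKFB1, which encodes a regulator of glycolysis, had a log2 fold change of 3.76, C2orf72 4.18, LRRC2 3.67 and the bicarbonate transporter SLC4A4 3.32. PFKFB1 at progression was at 19.2, 64.3 and 95 CPM in patients 2, 3 and 5, whose progression libraries were rich in albumin RNA. It was at 4.09 and 9.8 CPM in patients 1 and 4. In patient 1 C2orf72 was at 0 CPM at baseline and 0.569 CPM at progression. The genes lower in 5 of 5 pairs were the zinc transporter SLC39A4 (-2.20), ZNF580 (-2.23), the immediate early gene IER3 (-1.80), OLFML2B (-2.77) and SHISA5 (-1.30). The edgeR adjusted p was 0.263 for all of them, and DESeq2 called all 10. Among these genes OLFML2B was called without patient 2, at -3.20, where progression and the MALAT1 split cannot be told apart. At progression GABARAPL1 was at 12.5 CPM in patient 2 and between 40.1 and 42.4 CPM in the other patients, and IER3 at 50.2 CPM against at most 9.88 CPM.

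Of the 31 panel genes, 0 passed the edgeR test, over all genes or adjusted over the list alone. CDK6, a target of palbociclib, was higher in 5 of 5 pairs, with a log2 fold change of 2.04 (SE 0.58) and an edgeR adjusted p of 0.263. Its mean was 10.2 ± 9.17 CPM at baseline and 43.7 ± 37.6 CPM at progression (SD, n = 5). CDK4 had a log2 fold change of 0.15 (0.04 to 0.28 with 1 pair left out) and CDK2 of 0.56 (0.14 to 0.76). CCND1, which encodes cyclin D1, was lower in 5 of 5 pairs (-1.73), as was the CDK inhibitor CDKN1A (-0.98). Of all 18543 genes tested, 16.3% moved the same way in 5 of 5 pairs, so this alone does not set these genes apart. The CDK inhibitor CDKN1B had a log2 fold change of -0.70, with -0.01 in patient 1 and -2.22 in patient 4, and -0.35 without patient 4. The largest changes of CDK6 (3.86) and CCND1 (-4.67) were in patient 1. The progression library of that patient was at 0 CPM for the luminal gene FOXA1 and 40100 CPM for the marrow marker HBB. A change in cell content cannot be told apart there from a change within tumour cells. With 1 pair left out CDK6 ranged from 1.57 to 2.42 and CCND1 from -2.07 to -1.16. The log2 fold change was 0.28 for the tumour suppressor RB1, 0.13 for RBL1, 0.42 for RBL2, 0.24 for CCNE1 and 0.11 for CCNE2. The receptor genes had wide intervals: ESR1 was at -0.98 (-2.95 to 0.99), PGR at -1.59 (-5.50 to 2.31) and ERBB2 at 0.32 (-1.88 to 2.52). With 1 pair left out ESR1 ranged from -1.51 to -0.30 and PGR from -2.69 to -0.45, and the sign of RB1, RBL1, CCNE1, CCNE2 and ERBB2 turned. FGFR1 was at 1.25 and was higher in 4 of 5 pairs. DESeq2 called CDK6 (2.10) and FGFR1 (1.31) and no other panel gene.

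**Figure D1:**
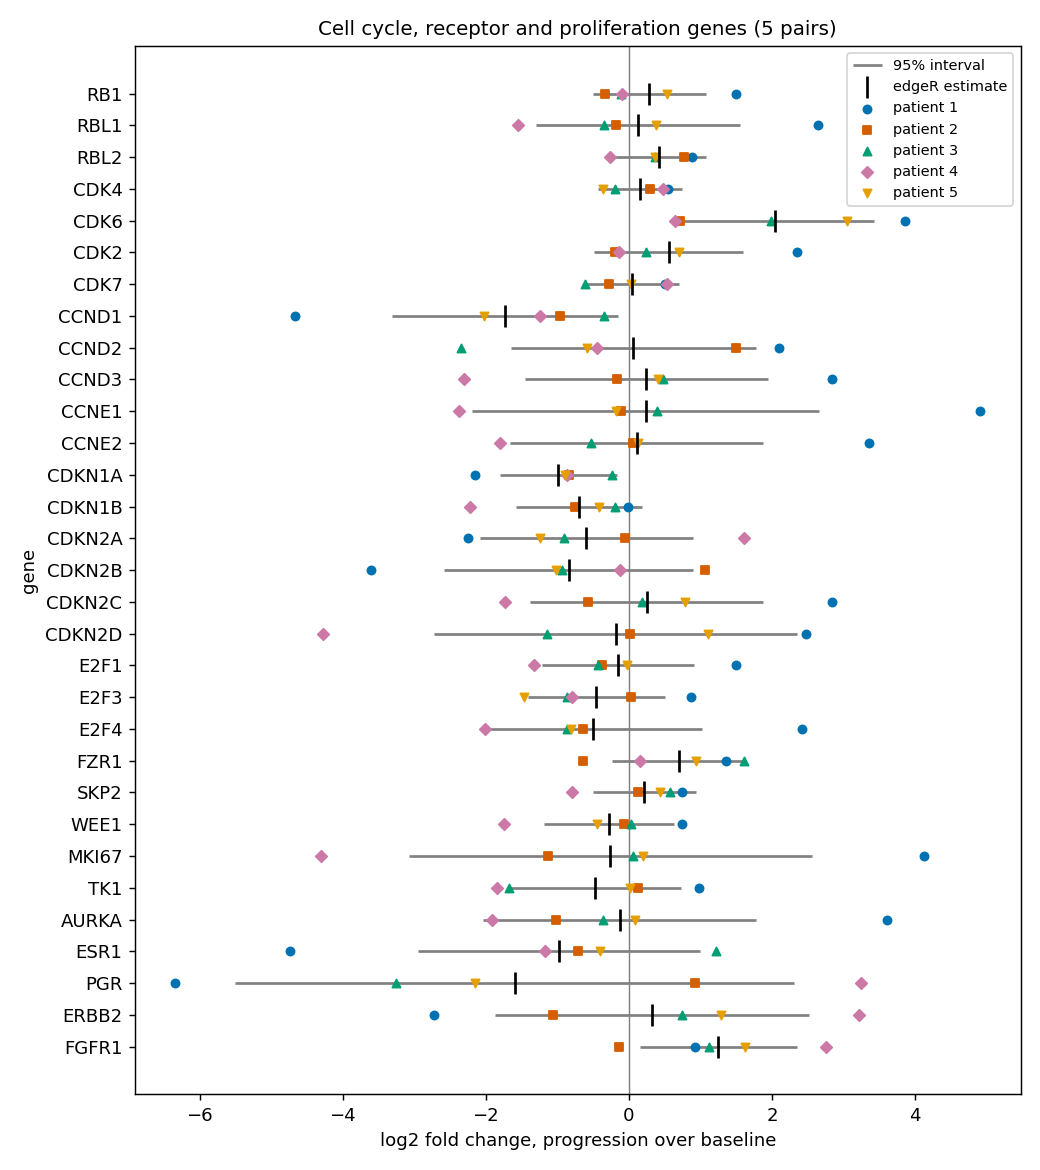
Log2 fold change, progression over baseline, of 31 panel genes (x axis) by gene (y axis). Black ticks are edgeR estimates with 95% intervals in grey and coloured points are the 5 patients; CDK6 lies above 0 and CCND1 below 0 in every patient, while MKI67 spans -4.31 to 4.12.

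Proliferation genes were higher at progression in some patients and lower in others. The mitosis list of 27 genes did not pass the camera test (median log2 fold change 0.03, adjusted p 0.782): its score differed by 3.97 in patient 1, -0.84 in patient 2, 0.00 in patient 3, -2.70 in patient 4 and 0.31 in patient 5. The list of E2F targets and DNA replication genes did not pass either (median 0.13, adjusted p 0.313), with 20 of 28 members higher and 8 lower. The members with the smallest p were CENPA and POLA1. MKI67, which encodes the proliferation marker Ki-67, went from 155 to 2700 CPM in patient 1 and from 1150 to 58.0 CPM in patient 4. Marrow markers were high in libraries of both these patients: HBB held 1.74% of counts at baseline and 3.50% at progression in patient 1, and 1.18% at baseline in patient 4. The marrow score differed by 3.51 in patient 1, 1.26 in patient 2, 2.37 in patient 3, -13.17 in patient 4 and 3.28 in patient 5. At the preset correlation the mitosis list was called lower without patient 1 (median -0.77, adjusted p 8.42e-04) and higher without patient 4 (0.62, adjusted p 8.62e-03), as was the E2F list (0.59, adjusted p 3.58e-03). Over all 5 pairs the estimated correlation was 0.972 for the mitosis and 0.914 for the E2F list, with which the adjusted p was 0.981 for both; it was not applied with pairs left out. At the preset correlation both lists were also called lower with the epithelial score as a covariate (-1.40 for mitosis, -0.82 for E2F) and higher with hepatocyte and marrow scores (1.25 and 0.87). With the MALAT1 term, which leaves the comparison to patient 2, the mitosis median was -0.86.

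Genes of luminal breast cells and oestrogen receptor targets fell in the camera test. Of 15 luminal identity genes 13 were lower (median -1.27, adjusted p 2.66e-04), and of 25 oestrogen receptor targets 18 were lower (median -0.54, adjusted p 0.0121). With an estimated correlation the adjusted p was 0.889 for both lists. Both scores were lower in 5 of 5 patients (exact sign-flip p = 0.0625, the smallest possible), though the oestrogen receptor target score by only -0.01 in patient 2 and -0.08 in patient 4, against -3.20, -1.02 and -1.29 in patients 1, 3 and 5. By edgeR no member passed on its own. The target genes with the smallest p were TFF1 (-7.12), TFF3 (-4.48) and AREG (-1.82), and the luminal genes were AGR2 (-5.12), AGR3 (-4.57) and NAT1 (-3.08). DESeq2 called all 6 of them. AGR2 separated the 4 libraries rich in MALAT1 from the other 6. Epithelial markers also fell (median -0.77, adjusted p 1.42e-03, 0.899 with an estimated correlation), with PRSS8 at -2.06 and MUC1 at -2.57 (-3.36 to -1.68 with 1 pair left out). In patient 1 the luminal score differed by -6.24, and KRT8, a keratin of luminal cells, was at 208 CPM at baseline and 19.1 CPM at progression. Without patient 1 the oestrogen receptor target and epithelial lists no longer passed (medians -0.45 and -0.37), and the luminal median was -0.80. With a term for the MALAT1-rich libraries, which leaves the comparison to patient 2, the median was -0.22 for the oestrogen receptor target list and -1.05 for the luminal list. Neither of these 2 lists passed with the epithelial score as a covariate (-0.26 and -0.21).

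**Figure D2:**
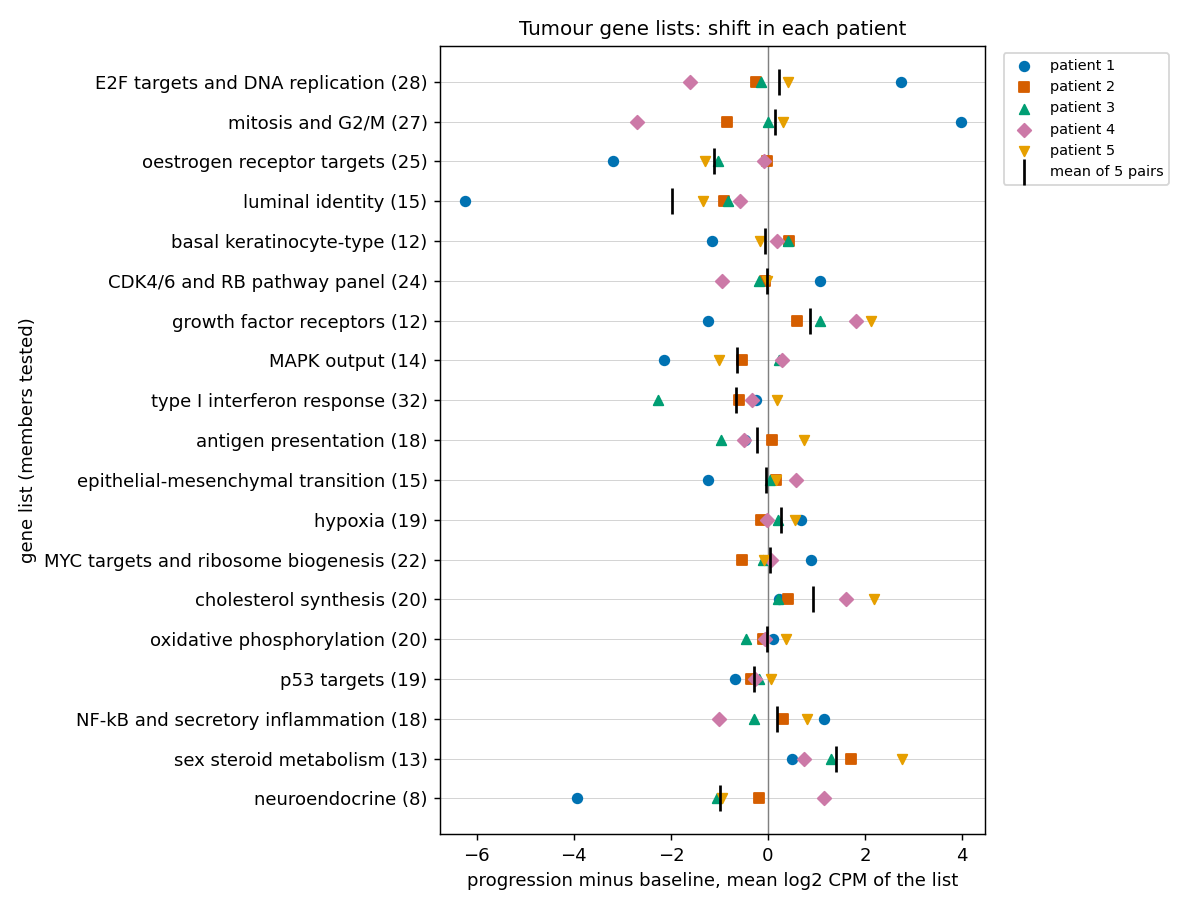
Progression minus baseline of the mean log2 CPM (x axis) for 19 tumour gene lists (y axis). Points are the 5 patients and black ticks their mean; the luminal identity list is below 0 in all 5 patients, from -6.24 to -0.58, and the mitosis list spans -2.70 to 3.97.

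Hepatocyte genes rose most: 24 of 24 had a positive log2 fold change (median 3.84, adjusted p 7.99e-07, 0.889 with an estimated correlation). The score differed by 13.27 in patient 5, 6.04 in patient 2, 2.82 in patient 3, 0.43 in patient 1 and -2.58 in patient 4. Albumin (ALB) held 2.92%, 5.09% and 4.60% of counts in the progression libraries of patients 2, 3 and 5, and 1.07% in the baseline library of patient 3. The Wilson 95% intervals of all shares given here reach at most 0.00765 percentage points to either side, for counting error only. Without patient 5 the hepatocyte median was 2.36. The members with the smallest p were APOB (3.87), TF (5.20) and CYP2C8 (3.88, and 2.58 to 5.27 with 1 pair left out). By edgeR no member passed on its own, and DESeq2 called these 3. Lists that rose beside it were cholesterol synthesis (19 of 20 higher, median 0.86, adjusted p 1.59e-04) and sex steroid metabolism (12 of 13 higher, median 0.96, adjusted p 3.19e-04). Both had an adjusted p of 0.889 with an estimated correlation, and liver also expresses genes of both. Among cholesterol genes, INSIG1 (1.46) and SC5D (1.83) passed when adjusted over the list alone. Steroid genes were led by the oestrogen sulfotransferase SULT1E1 (7.99), HSD17B4 (1.31) and SRD5A1 (1.55), of which SULT1E1 and HSD17B4 passed when adjusted over the list alone. The cholesterol median was 0.52 without patient 4 or 5, and the steroid median was 0.61 without patient 3. With a term for the MALAT1-rich libraries, which leaves the comparison to patient 2, the cholesterol median was 0.06. With the hepatocyte score as a covariate the steroid median was 0.33, and with hepatocyte and marrow scores the cholesterol list did not pass (0.25).

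**Figure D3:**
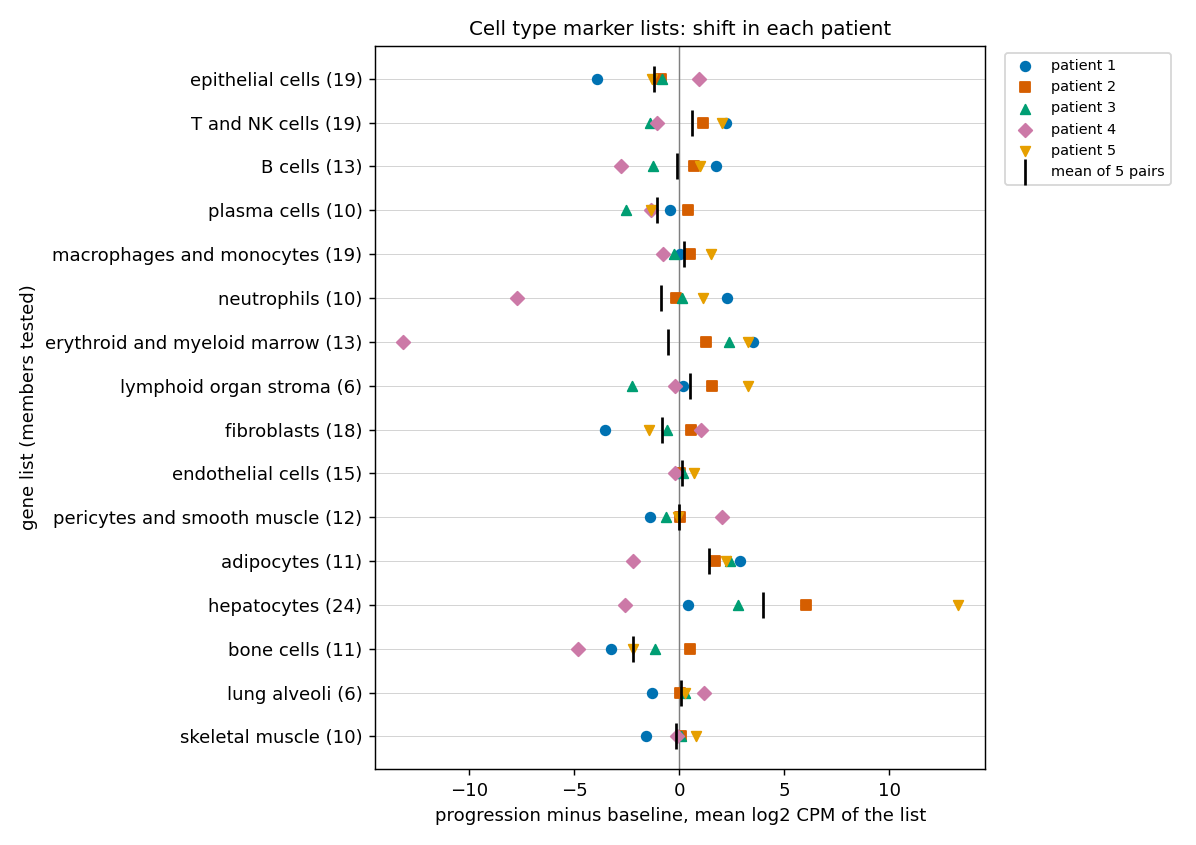
Progression minus baseline of the mean log2 CPM (x axis) for 16 cell type marker lists (y axis). Points are the 5 patients and black ticks their mean; hepatocyte markers reach 13.27 in patient 5, and marrow markers fall to -13.17 in patient 4.

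Growth factor receptor genes rose as a list (8 of 12 higher, median 1.26, adjusted p 1.93e-03, 0.889 with an estimated correlation). The receptor score was higher in 4 of 5 patients, by 0.59 to 2.12, and differed by -1.24 in patient 1 (exact sign-flip p = 0.25). EGFR (3.17), FGFR3 (2.52), MET (2.75) and INSR (1.27) passed by edgeR when adjusted over the list alone, and 0 passed over all genes. DESeq2 called EGFR, FGFR3 and MET over all genes. Adipocyte genes rose (7 of 11 higher, 4 lower, median 1.90, adjusted p 6.04e-03), led by AQP7 (3.89), THRSP (4.18) and GPD1 (3.49), as did T and NK cell genes (18 of 19 higher, median 0.63, adjusted p 0.0292), led by KLRD1 (2.04) and GZMA (1.12, and 0.71 to 1.70 with 1 pair left out). The T and NK cell score was lower in 2 of 5 patients, by -1.38 in patient 3 and -1.07 in patient 4 (exact sign-flip p = 0.5). With an estimated correlation the camera adjusted p was 0.889 for the adipocyte list and 0.981 for the T and NK cell list. The adipocyte list did not pass without patient 1 (median 1.03), nor the T and NK cell list without patient 1, 2 or 5 (0.26, 0.40 and 0.15), whose median was 1.12 without patient 3 and 1.05 without patient 4. With the epithelial covariate neither the adipocyte list (0.00) nor the T and NK cell list (-0.14) passed, and the latter turned direction. The receptor list did not pass with hepatocyte and marrow scores as covariates (0.81). Its median was -0.07 with the MALAT1 term, which leaves the comparison to patient 2.

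Interferon response genes fell (28 of 32 lower, median -0.59, adjusted p 1.22e-03, 0.942 with an estimated correlation), led by ISG15 (-1.77), IFI6 (-1.91) and BST2 (-1.65). Its score differed by -2.26 in patient 3, and the list did not pass without that pair (median -0.19). Plasma cell genes fell (9 of 10 lower, median -1.25, adjusted p 0.0121), led by MZB1 (-2.54), DERL3 (-1.96) and POU2AF1 (-2.15), and also did not pass without patient 3 (median -0.64). Immunoglobulin genes, products of plasma cells that the list does not hold, were not all lower: IGHA1 was at 3.08 and IGKC at 2.55, each higher in 5 of 5 pairs, and IGLC2 at -1.19. None of these 3, chosen after their values were seen, passed by edgeR, and DESeq2 called IGHA1 (3.15). Bone cell genes fell (10 of 11 lower, median -2.02, adjusted p 5.69e-04), led by ACP5 (-1.08), MEPE (-5.89, and -3.45 without patient 4) and IBSP (-5.75). The adjusted p of the plasma and bone cell lists was 0.889 with an estimated correlation. The bone cell median was -0.94 without patient 1. With the MALAT1 term, which leaves the comparison to patient 2, the median was 0.31 for plasma cells and 0.08 for bone cells.

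Heat shock genes fell (11 of 12 lower, median -0.81, adjusted p 9.50e-03, 0.889 with an estimated correlation), and 5 of them passed when adjusted over the list alone, among them HSPA1B (-1.67), DNAJB1 (-0.78) and HSPA6 (-1.33). Cytosolic ribosomal protein genes fell (23 of 24 lower, median -0.55, adjusted p 3.94e-03, 0.942 with an estimated correlation), led by RPL15 (-1.25), RPS19 (-0.98) and RPLP1 (-0.90). MAPK output genes fell (13 of 14 lower, median -0.63, adjusted p 0.0306, 0.894 with an estimated correlation), led by DUSP6 (-1.10), DUSP5 (-1.01) and CCND1. The MAPK score differed by -2.14, -0.53 and -1.01 in patients 1, 2 and 5, and by 0.23 and 0.29 in patients 3 and 4 (exact sign-flip p = 0.25). Immediate early genes, which respond to tissue handling, fell (17 of 21 lower, median -0.56, adjusted p 0.0473, 0.969 with an estimated correlation), led by IER3, BTG2 (-1.70) and CCN1 (-0.96). The heat shock list did not pass without patient 2 (median -0.72) and was at -0.51 without patient 1. The MAPK list did not pass without patient 1, 2 or 5 (-0.41, -1.01 and -0.58), and its median was 0.01 with the epithelial covariate. With the MALAT1 term, which leaves the comparison to patient 2, the median was -0.70 for the MAPK list and -0.05 for the ribosomal list. The immediate early list did not pass without patient 2, 3, 4 or 5 (-0.59, -0.26, -0.64 and -0.05) and was at -1.04 without patient 1. It turned direction with the hepatocyte covariate (0.20) and with hepatocyte and marrow covariates (0.62). In all, camera called 16 of 39 lists, 6 up and 10 down, and 0 with an estimated correlation, where the median correlation was 0.413. By fry, 0 lists moved on balance one way and 5 changed in either direction. Median, mean and test differed in sign for the hypoxia, mitosis, CDK4/6 panel, macrophage, neutrophil, basal, oxidative phosphorylation and skeletal muscle lists.

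The 10 libraries also split in a way the labels do not tie to single libraries. The labels' protocols give the same kit and the same 2 capture names for all samples. MALAT1, a nuclear non-coding RNA, held 3.12%, 1.42%, 3.30% and 0.88% of counts in the progression libraries of patients 1, 3, 4 and 5. It held at most 0.02% in the other 6, among them the progression library of patient 2. Between these 4 and 6 libraries, 49 genes were higher and 199 lower by more than 1 on the log2 scale without overlap. The count filter asks for enough counts in at least 5 libraries. It drops genes seen only in the 4 and keeps genes seen only in the 6, so 49 and 199 cannot be compared. Of the 210 ways to pick 4 libraries, 2 separated as many genes, this one included. RMRP, a non-coding RNA of a ribonuclease, differed by 5.41, 5.22, 6.05 and 6.04 within patients 1, 3, 4 and 5 and by -0.04 in patient 2. The small nucleolar RNA SNORA57 was at a log2 CPM of 3.13 to 7.53 in the 6 libraries and at most -2.68 in the 4. These genes were chosen after their values were seen. With a term for these 4 libraries, the comparison rests on patient 2 alone and 105 genes had an unadjusted p under 0.05.

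**Figure D4:**
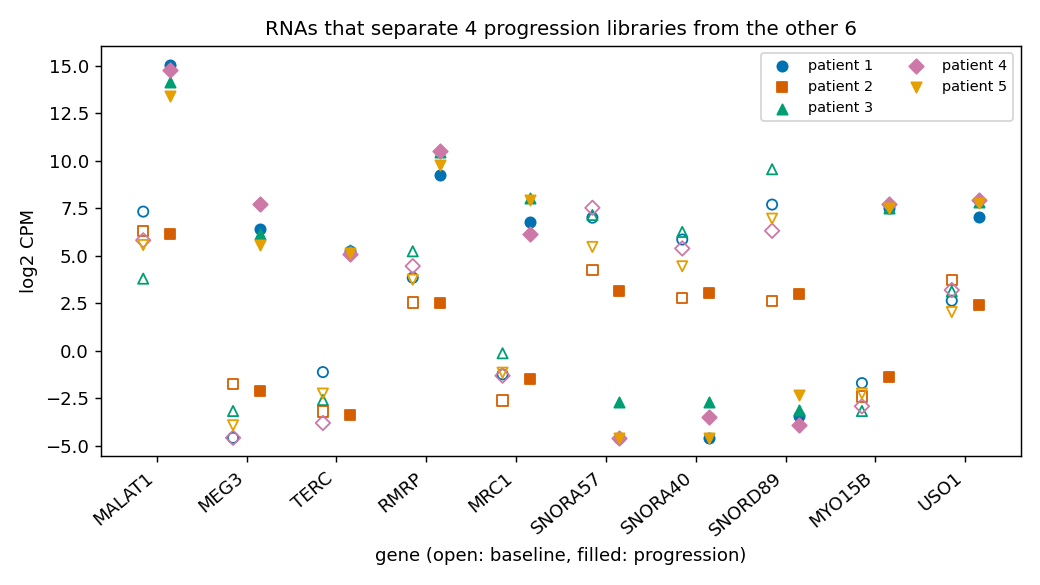
Log2 CPM (y axis) of 10 RNAs (x axis) in each library, open for baseline and filled for progression, with 1 colour per patient. Progression libraries of patients 1, 3, 4 and 5 stand apart from the other 6 for every RNA shown, and the progression library of patient 2 lies with the baselines.

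In the main test libraries of 1 patient were on average more alike than libraries of different patients, but not in every setting. The mean correlation of log2 CPM across genes was 0.822 for matched libraries against 0.775 over 120 matchings, and 5 matchings were as high (exact one-sided p = 0.0417). For 2 of 5 patients the best match of the baseline library was the patient's own progression library. The baseline library of patient 4 correlated at 0.862 with the progression library of patient 1 and at 0.793 with its own. HBB held 1.18% and 3.50% of counts in the first 2 of these libraries. Whether tissue content of the biopsies gives the likeness was not tested. The exact p was 0.0583 by Spearman, 0.108 on FPKM, and 0.208, 0.125 and 0.0833 without patient 2, 3 or 5.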

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

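The tests of explanations here were chosen after the result was seen. Only for the ratio test of hepatocyte genes was the bound set beforehand. That test compared the progression libraries of patients 5 and 3, which had the highest hepatocyte scores (12 and 11.9, against 9.93 in patient 2). It was therefore not blind to the hepatocyte result. A single library lay far from the other 4 of its group, by the ratio of its gap to the group's range, in 17 of 180 groups of values, where chance gives about 9.

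The progression library of patient 1 stood apart in HBB (3.50% of counts, ratio 0.987), the luminal score (1.36 against 6.05 to 7.16, ratio 0.809), the CDK4/6 panel score (ratio 0.828), RBL1 (0.873), CCND3 (0.765), CCNE1 (0.900) and AURKA (0.811). The baseline library of patient 4 stood apart in CCND3 (0.810), CCNE1 (0.918) and CDKN2D (0.724). The progression library of patient 2 stood apart in GABARAPL1 (3.65 against 5.33 to 5.41, ratio 0.954), LRRC2 (0.750), IER3 (0.749) and the lymphoid organ stroma score (0.861). Other such values were ALB at baseline of patient 3 (0.988), RB1 at baseline of patient 5 (0.813) and E2F1 at baseline of patient 1 (0.756).

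MALAT1, MEG3, TERC and RMRP were higher and small nucleolar RNAs lower in 4 of 5 progression libraries. Hepatocyte RNA is argued against, since the hepatocyte score differed by -2.58 in patient 4, 1 of those 4 pairs. A different capture or library preparation stays open: non-coding genes made up 55.6% of the 248 separating genes and 14.4% of those tested (odds ratio 7.83), but the split was noticed on non-coding RNAs, so this restates the pattern and decides nothing. Progression itself stays open, because only patient 2 has both libraries on 1 side, where MALAT1 differed by -0.14. The split and progression cannot be told apart in the other 4 patients.

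The hepatocyte score was higher at progression in 4 of 5 patients, in patient 1 by 0.43. Liver tissue in the biopsy is a candidate explanation: across 24 hepatocyte genes the log2 ratio between the progression libraries of patients 5 and 3 had an SD of 0.22, against a median of 0.44 for expression-matched genes, and 9 of 1000 matched draws were as low. The bound set for this test lay barely above that SD. The library split as the whole cause is argued against by 2 single pairs. The score differed by 6.04 in patient 2, whose libraries lie on 1 side of the split. It differed by -2.58 in patient 4, whose libraries lie on both sides. With a term for the split, which leaves the comparison to patient 2, the hepatocyte median was 6.54, against 3.84 without the term. Expression of these genes by the tumour was not tested.

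Luminal and oestrogen receptor target genes were lower. A lower share of epithelial cells could contribute and cannot be told apart from a change within them. Luminal genes outside the epithelial list fell further than epithelial markers by -1.07 on average (SE 0.64), but by -0.53 without patient 1, where the difference was -3.22. The difference was -1.85 in patient 4 and -0.07, -0.01 and -0.19 in patients 2, 3 and 5. With the epithelial score as a covariate the luminal median went from -1.27 to -0.21 and did not pass, though 3 of the 15 luminal genes are also in that score, and in patient 4 the epithelial score was higher. The library split cannot be told apart either. The luminal score differed by -0.91 in patient 2, the only pair on 1 side of the split. With a term for the split, which leaves the comparison to patient 2, the luminal median was -1.05.

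A count of 0 genes cannot be weighed against other splits of the libraries, since all 100 drawn give at least 0 whatever the data (the highest other gave 0). For lists chance was not excluded: 56 of 100 splits gave at least 16, and the highest other gave 24. Some of the 100 splits repeat the same fit, since the side that a pair kept together is put on does not change a fit blocked on patient. They are not 100 separate draws. Of the 100 splits 86 part 1 or 3 pairs, so that their comparison rests on fewer patients, and 14 part all 5. Pairs kept together still add to the residual spread. In a separate run, every split that parts all 5 pairs was fitted, 16 with the real one included. Of these 16 splits, 9 gave at least 16 lists and the highest other gave 24. These 16 are too few for a share under 0.05; DESeq2 called 1893 genes in the real one and at most 919 in another, so 1 of 16 was as high.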

How the results depend on the processing

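Settings with covariates for hepatocyte or marrow scores, without patients 1 and 4, with the library-type term or with GC correction were chosen after seeing the data. The cause of the changes below was not tested. DESeq2 called 1893 genes against 0 with edgeR, and 2 panel genes. In simulation 129 of its 240 calls were false, with 18313 genes unchanged. That share depends on how many genes were changed in the simulation, so it gives no share for the 1893. Leaving out pairs gave 0 to 40 genes, and every other setting gave 0, with between 105 (library-type term) and 4745 (voom) genes at an unadjusted p under 0.05. The median of all genes was -0.25 with FPKM at least 1 and -0.12 without patients 1 and 4 or with the library-type term. The count of lists went from 16 to 0 with an estimated correlation and to 0 with fry.

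The oestrogen receptor target list had a median of -0.26 with the epithelial covariate, -0.68 without patients 1 and 4, and -0.54 with an estimated correlation and with fry. It was no longer called in any of these. With the library-type term, which leaves the comparison to patient 2, its median was -0.22 and the camera direction turned. Leaving out pairs gave -0.57 to -0.44. The E2F list had -0.82 with the epithelial covariate, 0.87 with hepatocyte and marrow covariates, -0.05 without patients 1 and 4, -0.19 with the library-type term, and -0.41 to 0.59 without single pairs. The E2F list became called with the first 2 of these, in opposite directions. The mitosis list had -1.40, 1.25, -0.17 and -0.86 in the same settings, called in the first 2. The last of these rests on patient 2 alone. The mitosis list had -0.30 with the hepatocyte covariate, and -0.77 to 0.62 without single pairs. The mean mitosis score difference over the 5 pairs was 0.15 and, on FPKM, -0.06. Other lists that no longer passed were, with no replicate block, MAPK (-0.66), T and NK cells (0.53) and immediate early genes (-0.48), and without a count filter adipocytes (0.35). On FPKM they were T and NK cells and adipocytes (0.14 each), with 1 CPM in 5 libraries or GC correction immediate early genes (-0.54 and -0.56), and with the epithelial covariate heat shock (-0.43). With the hepatocyte covariate they were MAPK (-0.46), T and NK cells (-0.05), adipocytes (1.15) and heat shock (-0.45), and with hepatocyte and marrow covariates T and NK cells (0.36), heat shock (-0.71) and ribosomal proteins (-0.42). Without patients 1 and 4 they were MAPK (-0.69), T and NK cells (0.72) and bone cells (-0.48). Lists that became called were, with the epithelial covariate, the CDK4/6 panel (-0.74), B cells (-1.28), neutrophils (-2.97) and marrow (-1.70). With the hepatocyte covariate they were antigen presentation (-0.58), macrophages (-0.91), neutrophils (-2) and marrow (-0.66), and with hepatocyte and marrow covariates antigen presentation (-0.84), macrophages (-1) and fibroblasts (-1.42). Without a count filter they were p53 targets (-0.25) and fibroblasts (-0.72), and on FPKM p53 targets (-0.32) and antigen presentation (-0.39). Without patients 1 and 4 it was marrow (2.25). With the library-type term, which leaves the comparison to patient 2, the median was 2.32 for marrow and -0.54 for MYC targets. A list's own score as covariate left hepatocytes at 0.06 and epithelial cells at 0.05. The excess in correlation of matched libraries was 0.035 by Spearman and 0.024 on FPKM, neither called, and 0.031 to 0.060 without single pairs.

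Of 1852 values of 89 named genes in other settings, 1699 kept direction and side of the threshold, 52 became called (51 by DESeq2) and 101 changed sign, none of them called. Changed log2 values were, with no replicate block: CCND3 -0.05, CDKN2B 0.18, CDKN2D 0.06, E2F4 0.04, MKI67 0.65, AURKA 0.57. Without a count filter: CDK7 -0.02. On FPKM with pseudocount 1 and with FPKM at least 1: RBL1 -0.02, CDK4 -0.09, CDK7 -0.19, CCND3 -0.03, CCNE2 -0.01, SKP2 -0.04. With pseudocount 0.1: RBL1 -0.06, CDK4 -0.10, CDK7 -0.21, CCND2 -0.16, CCND3 0, CCNE2 -0.01, SKP2 -0.04. With the epithelial covariate: RB1 -0.15, RBL1 -0.86, CDK2 -0.07, CDK7 -0.02, CCND2 -0.58, CCND3 -0.99, CCNE1 -1.27, CCNE2 -1.05, CDKN2A 0.36, CDKN2C -0.85, SKP2 -0.14, PGR 0.87. With voom: CDK4 -0.02, CDK7 -0.14, CCND2 -0.28, CCNE2 -0.12. With the hepatocyte covariate: RBL1 -0.06, CCND3 -0.05, CCNE2 -0.04, CDKN2C -0.04. With hepatocyte and marrow covariates: E2F1 0.27, E2F3 0.18, E2F4 0.52, WEE1 0.11, MKI67 1.01, AURKA 1.06, ERBB2 -0.86. Without patients 1 and 4: RBL1 -0.06, CDK4 -0.10, CDK7 -0.30, CCND2 -0.50, CCNE2 -0.13, ESR1 0. With the library-type term: POLA1 -0.42, NAT1 0.87, DERL3 0.22, POU2AF1 0.35, RB1 -0.34, RBL1 -0.18, CDK2 -0.20, CDK7 -0.28, CCND3 -0.18, CCNE1 -0.11, CDKN2B 1.06, CDKN2C -0.57, CDKN2D 0.01, E2F3 0.03, FZR1 -0.64, TK1 0.12, PGR 0.96, ERBB2 -1.06, FGFR1 -0.14. With GC correction: CDK7 -0.03, CCND2 -0.03. Ranges without single pairs were AURKA -0.81 to 0.38, CCND2 -0.49 to 0.69, CCND3 -0.36 to 0.83, CCNE1 -0.54 to 0.93, CCNE2 -0.54 to 0.62, CDK7 -0.09 to 0.24, CDKN2C -0.34 to 0.76, CDKN2D -0.93 to 0.61, E2F1 -0.55 to 0.14, ERBB2 -0.39 to 1.03, MKI67 -1.12 to 0.58, RB1 -0.02 to 0.44, RBL1 -0.43 to 0.56 and WEE1 -0.55 to 0.06.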

Other observations

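Other cell types were uneven between the biopsies of a patient. The erythroid and myeloid marrow score differed by -13.17 in patient 4 and by 3.51 in patient 1, and the neutrophil score by -7.71 and 2.27. Fibroblast markers differed by -3.52 in patient 1 and 1.04 in patient 4. The adipocyte score was higher in 4 of 5 patients and -2.22 in patient 4. Endothelial markers differed by at most 0.70. Of these lists only that of adipocytes passed the camera test, and it had an adjusted p of 0.889 with an estimated correlation.

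Lists that did not pass included antigen presentation (median -0.14, adjusted p 0.579), epithelial-mesenchymal transition (-0.18, 0.900), hypoxia (-0.01, 0.320), MYC targets (0.02, 0.900), oxidative phosphorylation (-0.04, 0.900), p53 targets (-0.20, 0.272), NF-kB and secretory inflammation (0.08, 0.579), neuroendocrine genes (-0.80, 0.202), basal genes (-0.06, 0.782), the CDK4/6 panel (0.08, 0.900), B cells (0.22, 0.900), macrophages (-0.32, 0.900), neutrophils (-0.53, 0.544), marrow (1.88, 0.579), lymphoid organ stroma (0.36, 0.579), fibroblasts (-0.67, 0.0765), endothelial cells (0.35, 0.544), pericytes (-0.38, 0.900), lung alveoli (0.02, 0.985), skeletal muscle (-0.09, 0.900) and mitochondrially encoded genes (-0.19, 0.782), by camera. At the preset correlation some of them passed with 1 pair left out: marrow without patient 4 (2.69), fibroblasts without patient 2 or 4 (-1.02 and -1.30), antigen presentation without patient 5 (-0.41) and mitochondrially encoded genes without patient 3 (-0.61). Over all 5 pairs their estimated correlations were 0.910, 0.796, 0.423 and 0.839, and no list passed with them. Other settings under which some of these lists passed are given with the effects of the processing.

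MRC1, a macrophage receptor gene, was 8.01, 8.17, 7.48 and 9.08 higher on the log2 scale at progression in patients 1, 3, 4 and 5 and 1.15 higher in patient 2, while the macrophage list did not pass. It is among the genes that separate the 4 MALAT1-rich libraries. Of the 199 genes lower in those libraries, 42 were zinc finger genes with a ZNF symbol. Both facts were noticed after the values were seen.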
